A study of Mus musculus with 6 samples.

How the data were processed

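Gene expression in inguinal white adipose tissue was measured by RNA sequencing in 6 male C57BL/6J mice, 3 given distilled water and 3 given 300 ppb sodium arsenite in drinking water for 9 weeks. Groups were taken from the treatment stated for each sample. Per the labels' protocols, tissue was snap-frozen, RNA was extracted with a kit for lipid-rich tissue, and reads were aligned to GRCm38, giving 20000000 mapped reads per sample. The submitters' processing notes name Bowtie2, HISAT and RSEM, without versions or roles. The software behind the comparison table, the scaling between libraries and the gene filter are not given in the sources used here. All 6 library labels share a flow cell lane, so no batch could be separated.

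The authors deposited a signal per group, the mean over its samples of a gene abundance on a count-like scale that is neither whole-number counts nor a per-million unit. These means summed to 8608581 for water and 7716846 for arsenite, and the lowest average of both means was 5.11. Per the file headers, the authors also deposited a log2 ratio of treatment over control for each gene. Recomputing it from the means showed that it equals the log2 of the ratio after 0.574 is added to each mean, to within 3.62e-08, so it understates the ratio of low genes. A value between 0 and 1, headed PPEE, was deposited per gene. PPEE is the name that the EBSeq method uses for a posterior probability of equal expression, and it is not a p-value. Columns headed control and treatment were read as water and arsenite. The deposited gene length and gene ontology annotation were also used.

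The tests fixed before the data were examined needed values per mouse: a count model or a linear model across genes, a competitive gene set test, and exact permutation of marker levels. Values per mouse were not analysed here, so those tests, their SDs, left-out replicates and other splits of the samples were not run. In their place a gene was called at a PPEE of at most 0.05, a bound chosen after the table was seen. The comparison of list medians with random lists, described below, replaced the gene set test and was also chosen then. A PPEE belongs to a gene alone, so no count adjusted over the list alone could be made.

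Most named genes follow a rule fixed before the data were examined, in terms of a p-value and its threshold, for which PPEE stood in once the table was seen. As applied, it named 17 sentinel genes whatever their values, the 12 called genes with the largest log2 ratio in each direction at a mean of at least 20 in 1 or both groups, and for each list up to 4 called members, or else the 2 of smallest PPEE. Predicted genes and clones were skipped (2 called genes in all), and the part of the rule asking that every arsenite sample lie beyond every water sample could not be applied. Outside the rule, and named after their values were seen, were Rps14, Rpl19, Rps6, Rps4y2, Rn18s, Rn28s1, Myh4, Acta1, Tpsb2, Mcpt4, Kit, Csf3r and Cxcr2. Fixed with the rule were 35 gene lists of pathways, cell types and quality markers. For a list with at least 5 measured members, its median log2 ratio was set among those of 10000 random lists drawn without its members and matched on mean level in 20 bins; the central range ran from the 2.5 to the 97.5 percentile. Intervals of 95% came from 10000 bootstrap draws over members, and genes are not replicates. Called genes were tested for over-representation of gene ontology terms of 10 to 500 genes, against the 11708 annotated genes in the table, by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment per direction. The groups of ribosomal and major urinary protein genes were formed from symbols after the values were seen. The trend of ratio on log10 gene length was removed with a lowess of span 0.3.

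Symbols of 22 genes had been turned into dates and were restored through gene identifiers; 13463 identifiers matched the RefSeq annotation of GRCm38.p6 and 27 did not. Shared sequence was the share of a gene's 50-base stretches, over its GENCODE M21 transcripts, that occur in other genes. The list method was tested on simulated data made from the 13490 genes: 12 of 200 lists without an effect fell outside the central 95%, and a planted list effect of -0.4 in short genes was recovered as -0.34 after length adjustment. Ratios were shuffled among genes of like mean level there, so list members did not vary together. The simulation thus gives no error rate for pathway lists. Alternatives were quantile normalization and upper-quartile scaling of the means, an added constant of 0.1, a minimum mean of 50, an absolute log2 ratio of at least 1, and, chosen after seeing the data, PPEE bounds of 0.01 and 0.1, random lists matched also on length in 10 bins each, and length-adjusted ratios. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.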

Results

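RNA sequencing was performed on inguinal white adipose tissue from 6 wild-type C57BL/6J male mice aged 15 weeks. This is a subcutaneous fat depot in which beige, heat-producing adipocytes can form. Mice drank either distilled water (3 mice, replicates 4, 6 and 8) or water with 300 ppb sodium arsenite, a trivalent inorganic arsenic salt (3 mice, replicates 9, 10 and FC16), for 9 weeks. The series title refers to adaptive thermogenesis, and the comparison asks which transcripts of this depot differed between arsenite-treated and water-treated males. The deposited values were group means for 13490 genes, together with the authors' log2 ratio and a posterior probability per gene that the groups were equally expressed (PPEE). Values per mouse were not analysed here, so the means below are the authors' means and carry no SD. The labels state 20000000 mapped reads per sample, and the depth of each library was not otherwise known. A gene was called changed at a PPEE of at most 0.05.

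Arsenite exposure was accompanied by lower expression of a fatty acid elongase and of sterol synthesis genes, and by higher expression of a set of genes that includes a water channel, a matrix glycoprotein and several transcription factors. In all, 99 of 13490 genes were called, 52 higher and 47 lower under arsenite. Elovl6, the elongase that converts palmitate to stearate, fell from an authors' mean of 4636 to 1432, 3.24-fold lower, in the authors' deposited table (log2 ratio -1.69, PPEE 3.05e-05). Cyp51, the lanosterol demethylase of cholesterol synthesis, fell from 795 to 353, with a log2 ratio of -1.17 and a PPEE of 5.03e-06 in the authors' deposited table. Aqp1, a water channel abundant in capillary endothelium, rose from 718 to 1555, 2.17-fold higher (log2 ratio 1.11, PPEE 0.000768 in the authors' deposited table). Sizes were moderate: the median absolute log2 ratio over the 99 called genes was 0.53, and 11 of them (6 higher, 5 lower) had an absolute log2 ratio of at least 1.

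**Figure D1:**
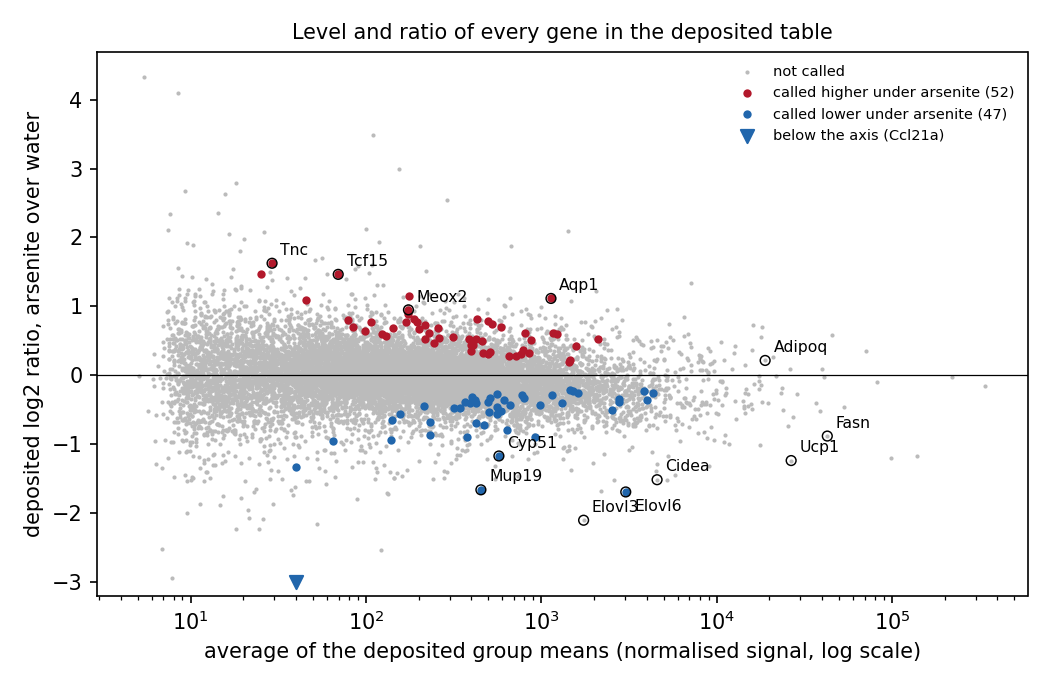
Deposited log2 ratio of arsenite over water (vertical axis) against the average of the authors' group means (horizontal axis, log scale, normalised signal) for 13490 genes. Red points are the 52 genes called higher, blue points the 47 called lower, grey points genes not called; open circles mark named genes, of which Ucp1, Cidea, Elovl3, Fasn and Adipoq were not called. The triangle marks Ccl21a, whose ratio lies below the axis because its arsenite mean is listed at 0.

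Among the called genes with larger increases, Tnc, encoding the matrix glycoprotein tenascin C, rose from 14.0 to 44.4 (log2 ratio 1.63 in the authors' deposited table). Tcf15 and Meox2, transcription factors that act together in capillary endothelium, rose from 36.7 to 102 and from 119 to 231, with log2 ratios of 1.46 and 0.95 in the authors' deposited table. Cldn15, a tight junction claudin, rose from 109 to 243, and Rufy4, a regulator of autophagosome formation, from 29.1 to 62.4 (log2 ratios 1.14 and 1.09 in the authors' deposited table). Btnl9 rose from 121 to 226 and Ushbp1 from 310 to 545 (log2 ratios 0.89 and 0.81 in the authors' deposited table). Csf2rb, a shared receptor subunit for several cytokines, rose from 136 to 240 (log2 ratio 0.82 in the authors' deposited table). Lnx1, an E3 ubiquitin ligase, and Kank3 had log2 ratios of 0.80 and 0.79 in the authors' deposited table. Rpl39l, a paralogue of a ribosomal protein gene, rose from 13.1 to 37.2, a log2 ratio of 1.46 in the authors' deposited table. The PPEE of these genes and Aqp1, 12 in all, ranged in the authors' deposited table from 8.5e-09 for Tcf15 to 0.0385 for Kank3.

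Among the called genes with larger decreases, Mup19, of the major urinary protein family, fell from 689 to 217 (log2 ratio -1.66 in the authors' deposited table). Its 50-base stretches all occur in other transcripts as well (100%, in 23 other genes), so its value is uncertain as that of a particular family member. Ccl21a, a chemokine of lymphatic endothelium and lymph node stroma, had a mean of 79.5 under water and was listed at 0 under arsenite, so no fold can be given. Of its 50-base stretches, 71.6% occur in other genes. Fdps and Sqle, farnesyl diphosphate synthase and squalene epoxidase, fell from 494 to 265 and from 299 to 164, with log2 ratios of -0.90 and -0.86 in the authors' deposited table (PPEE 0.000179 and 0.0488). Of the 50-base stretches of Fdps, 26.2% occur in other genes, against 0% for Sqle. Gys2, a glycogen synthase isoform, fell from 1205 to 645, and Nfil3, a clock-linked transcriptional repressor, from 184 to 95.2 (log2 ratios -0.90 and -0.94 in the authors' deposited table). Cyp2b10, of a detoxifying cytochrome family, fell from 57.6 to 22.6 and Tmem8 from 86.2 to 44.2 (log2 ratios -1.33 and -0.95 in the authors' deposited table). Sdc4, a heparan sulphate proteoglycan, fell from 814 to 468 and Slc7a6, an amino acid transporter, from 590 to 359 (log2 ratios -0.80 and -0.72 in the authors' deposited table). In GRCm38, the gene span of Elovl6, exons and introns together, lies on chromosome 3 at 129532386 to 129638495 and that of Cyp51 on chromosome 5 at 4080674 to 4104697. Aqp1 spans 55336299 to 55348555 on chromosome 6 and Ccl21a 42772860 to 42773991 on chromosome 4.

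The called genes with lower expression also held 8 cytosolic ribosomal protein genes, among them Rps14, Rpl19 and Rps6, picked after their values were seen, whose products are structural parts of the ribosome. Rps14 fell from 3139 to 2405 and Rpl19 from 3106 to 2447 (log2 ratios -0.38 and -0.34 in the authors' deposited table). Of the gene ontology terms carried by the deposited annotation, translation was over-represented among the called lower genes (8 of 227 genes against 0.834 expected, one-sided Fisher's exact test, adjusted p = 0.000416). All 8 were those ribosomal protein genes, and genes are not independent of each other. By the same Fisher's exact test, pancreas development had a smaller adjusted p (3.92e-05) through 7 of the same genes, so the term labels need caution. Of 1167 terms tested per direction, 6 passed an adjusted p of 0.05 for the lower genes and 0 for the higher genes, where the smallest adjusted p was 0.734. Ratios also followed gene length, with a Spearman's rho of 0.208 across genes, which are not independent replicates. The median ratio was -0.22 in the shortest 10% of genes and 0.04 in the longest 10%, and the shortest 10% held 16 of the 47 lower calls and 2 of the 52 higher calls. All 76 measured cytosolic ribosomal protein genes, a group formed after the values were seen and without most paralogues, had ratios below 0 (median -0.24). That median was at percentile 7.74 of random lists matched on level, inside the central 95%, and at 99.9, above it, with length matched too. With paralogues, 82 of 84 lay below 0, the exceptions being Rpl39l, called higher, and Rps4y2, not called and named after its value was seen. The median of the 76 was -0.07 under quantile normalization, with 24 of them above 0, and 0.0069 after the length trend was removed. The ribosomal RNA genes Rn18s and Rn28s1, also picked after their values were seen, made up 3.83% of the summed means under water and 1.88% under arsenite.

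**Figure D2:**
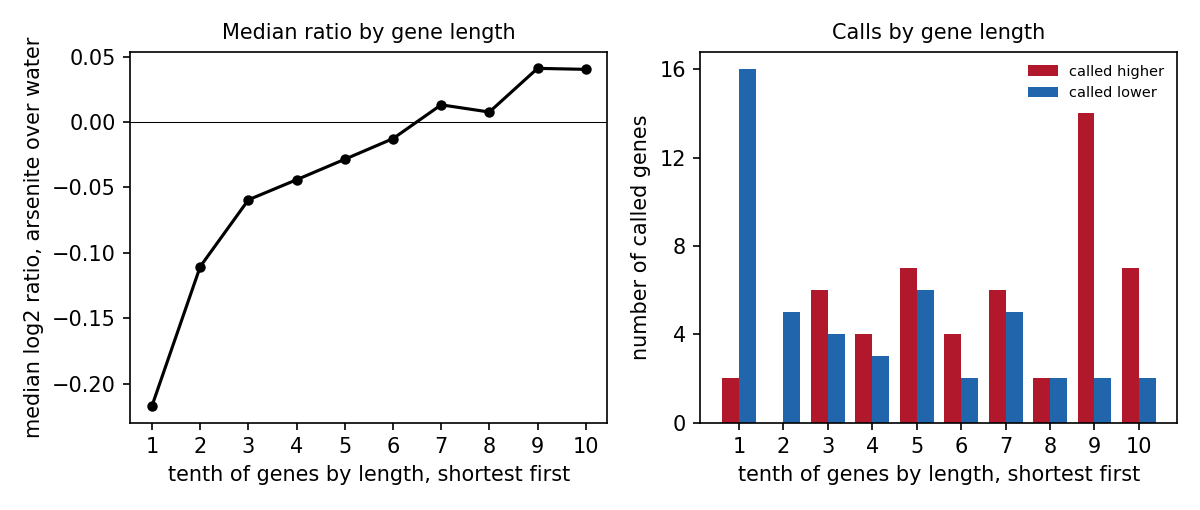
Left, the median deposited log2 ratio of arsenite over water in 10 equal groups of 13490 genes ordered by length; right, the number of called genes in each group, red for higher and blue for lower. The median runs from -0.22 in the shortest group to 0.04 in the longest, and the shortest group holds 16 lower and 2 higher calls.

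The thermogenic genes had lower means under arsenite, but none was called. Ucp1, the uncoupling protein through which beige and brown adipocytes release heat (chromosome 8, 83290348 to 83298456), had an authors' mean of 37406 under water and 15854 under arsenite, a log2 ratio of -1.24 with a PPEE of 0.999 in the authors' deposited table. The lipid droplet protein gene Cidea had means of 6787 and 2372, and Dio2, the deiodinase that activates thyroid hormone, 3332 and 1035. Elovl3, a cold-induced elongase, had 2832 and 658. The PPEE values of Cidea, Dio2 and Elovl3 in the authors' deposited table were 0.995, 0.977 and 0.985. Cox8b and Ppargc1a, a muscle-type cytochrome oxidase subunit and a coactivator of mitochondrial biogenesis, had log2 ratios of -1.14 and -0.76 in the authors' deposited table (PPEE 0.994 and 0.996). Prdm16, a determinant of beige fate, and Adrb3, a beta-adrenergic receptor of adipocytes, had log2 ratios of -0.10 and 0.21 in the authors' deposited table. Of the 35 measured members of the thermogenic list, 30 had ratios below 0 and 5 above, and the median was -0.70 (95% bootstrap interval over members -1.04 to -0.37). That median lay at the 0 percentile of 10000 random lists matched on mean level. The members with the smallest PPEE were Esrrg and Kng2, at log2 ratios of -0.91 and -1.72 in the authors' deposited table. Of all 13490 genes, 12816 had a PPEE above 0.9 in the authors' deposited table. Values that high are therefore common to most genes and not particular to the thermogenic ones. The spread between mice behind the posterior values of the thermogenic genes could not be examined.

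Mitochondrial gene groups lay low as well. All 54 nuclear oxidative phosphorylation genes had ratios below 0, with a median of -0.57 (interval -0.61 to -0.50) and no calls. That median was -0.34 after the length trend was removed and -0.37 under quantile normalization. Uqcr10, a subunit of complex III, had means of 2100 and 1015, and Atp5g3, of ATP synthase, 4052 and 3155. Of 24 tricarboxylic acid cycle and pyruvate genes, 23 lay below 0 (median -0.58, 0 called), with Pdhb at 7498 and 4318 and Pdha1, both subunits of pyruvate dehydrogenase, at 9702 and 6482. Of 30 fatty acid oxidation genes, 27 lay below 0 (median -0.39, or -0.22 under quantile normalization, 0 called). Cpt1a, which commits fatty acids to mitochondrial oxidation, had 312 and 435, and Acot1, an acyl-CoA thioesterase, had 57.5 and 17.7. The medians of these lists fell at the 0, 0 and 0.01 percentiles of matched random lists. Beside them, 18 of 20 skeletal muscle markers also had ratios below 0 (median -0.34, percentile 2.56, 0 called). Their median was -0.19 under quantile normalization and -0.22 after the length trend was removed. The ion channel subunit gene Cacng1 had means of 223 and 193 and the myoglobin gene Mb 126 and 280. The fast myosin gene Myh4 and the muscle actin gene Acta1, picked after their values were seen, had 61540 and 44653 and 28194 and 19956.

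Lipid synthesis genes were low as groups and held calls. Of 24 lipogenesis genes 1 fell by the test, Elovl6, and 23 had ratios below 0 (median -0.60, interval -0.88 to -0.38, percentile 0). Fasn, fatty acid synthase, had means of 55507 and 30107 with a log2 ratio of -0.88 in the authors' deposited table, and was not called. Of 24 cholesterol synthesis genes, 3 fell (Cyp51, Fdps and Sqle), 23 had ratios below 0, and the median was -0.52 (interval -0.84 to -0.39, percentile 0). Lipolysis genes were split, 12 above 0 and 8 below, with a median of 0.12 (interval -0.20 to 0.25, percentile 99.8; 0.27 under quantile normalization, 0.17 with upper-quartile scaling), with 1 called. This was Niacr1, the nicotinic acid receptor also called Hcar2, which rose from 125 to 214 (log2 ratio 0.77, PPEE 3.8e-07 in the authors' deposited table). General adipocyte genes had a median of 0.26 over 29 genes (percentile 100; 0.39 under quantile normalization), with 1 called. Klf15, a transcription factor of adipocyte and amino acid metabolism, rose from 415 to 518 (log2 ratio 0.32, PPEE 0.00696 in the authors' deposited table). The adipokine genes Adipoq and Lep had means of 17520 and 20333 and of 7741 and 10201, and Pparg, the master regulator of adipogenesis, 2332 and 2194, none called.

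Endothelial, matrix and preadipocyte genes lay high as groups, with no calls among the fixed markers. Of 18 endothelial markers, 17 had ratios above 0 (median 0.67, interval 0.59 to 0.79, percentile 100), and none was called. Cldn5, an endothelial claudin, had means of 114 and 326 with a PPEE of 0.221, and Flt1, a VEGF receptor, 303 and 485 with a PPEE of 0.102, in the authors' deposited table. Of 30 extracellular matrix genes, 27 lay above 0 (median 0.38, percentile 100, 0 called), with the matricellular genes Thbs1 at 43.6 and 129 and Thbs2 at 292 and 488. Preadipocyte and fibroblast markers had a median of 0.17 over 19 genes, 16 of them above 0 (percentile 99.8, 0 called), with Icam1 at 63.8 and 107 and Zfp423 at 123 and 200. Smooth muscle and pericyte markers were split, 6 above 0 and 6 below (median 0.14, percentile 97.0, inside the central 95%; 0.31 with a minimum mean of 50, outside it). After the length trend was removed their median was 0.09. Their members of smallest PPEE, Rgs5 and Smtn, had means of 247 and 366 and of 149 and 230, and none was called.

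**Figure D3:**
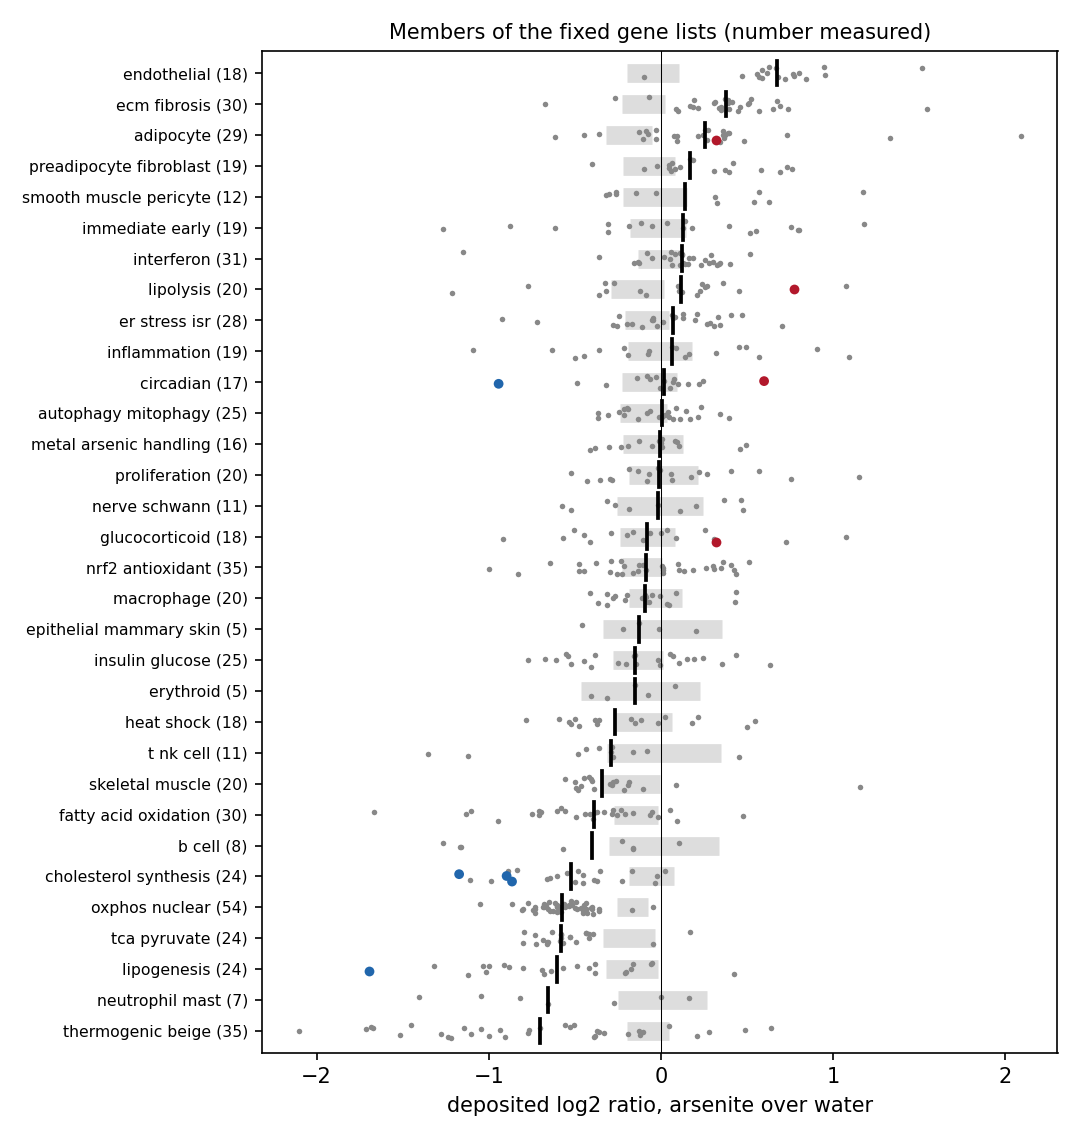
Deposited log2 ratios of arsenite over water for the measured members of 32 gene lists, with the number measured beside each name. Points are genes (red, called higher; blue, called lower; grey, not called), black bars are list medians, and pale bands span the central 95% of medians of 10000 random lists matched on mean level; the endothelial median of 0.67 and the thermogenic median of -0.70 lie outside their bands.

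Most measured immune cell markers had ratios below 0, as had 54.5% of all 13490 genes. Above 0 lay 10 of 19 inflammatory and 24 of 31 interferon genes. Measured were 8 of 20 B cell, 11 of 20 T and NK cell and 7 of 18 neutrophil and mast cell markers. Levels of the B cell and the T and NK cell markers were low, with median water means of 25.6 and 19.0. Of the 8 measured B cell markers 7 lay below 0 (median -0.40, percentile 0.65), with H2-Ob at 21.5 and 8.59 and Spib at 18.9 and 8.12. The 7 neutrophil and mast cell markers had a median of -0.66 (percentile 0.01), but the bootstrap interval over members, -1.04 to 0.00, was wide. The mast cell proteases carried it, with Cpa3 at 168 and 63.1, Cma1 at 143 and 68.9, Tpsb2 at 164 and 92.7 and Mcpt4 at 153 and 96.7. The mast cell receptor gene Kit had 55.4 and 55.5, and the neutrophil receptor genes Csf3r and Cxcr2 46.9 and 38.8 and 138 and 155, so the neutrophil markers were split; these 3 genes, Tpsb2 and Mcpt4 were named after their values were seen. Of the 11 T and NK cell markers 10 lay below 0 (median -0.29, percentile 3.07, inside the central 95% but outside it with length-adjusted ratios), with Cd3g at 16.6 and 6.17 and Lck at 22.7 and 10.1. Of the 20 macrophage markers 15 lay below 0 (median -0.09, percentile 22.6; -0.04 under quantile normalization, -0.03 with upper-quartile scaling). Their members of smallest PPEE, Itgax at 20.9 and 28.4 and Trem2 at 18.4 and 25.2, were among the 5 above 0. None of these markers was called. Inflammatory mediators had a median of 0.06 over 19 genes (percentile 78.5, 0 called; 0.03 under quantile normalization, 0.12 with upper-quartile scaling), with Nos2 at 15.4 and 33.5 and Cxcl9 at 181 and 269. Interferon-response genes had 0.12 over 31 genes (percentile 97.8, 0 called), with Mx1 at 38.1 and 16.8 and Tap1 at 186 and 266.

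Genes of arsenic handling and of the oxidative stress response showed no call. Mt1, a metallothionein, had means of 932 and 702 and Mt2 336.3 and 336.3, and As3mt, the arsenic methyltransferase, 84.1 and 83.6. The list of 16 metal and arsenic genes had a median of 0.00 (percentile 70.4; -0.02 under quantile normalization, 0.05 with upper-quartile scaling), with Slc39a8, a metal ion importer, at 41.4 and 57.1. The 35 NRF2 and antioxidant genes had a median of -0.08 (percentile 69.8; 0.04 under quantile normalization, 0.05 after the length trend was removed). Nqo1 and Hmox1, classical NRF2 targets, had means of 67.6 and 90.9 and of 257 and 259. The peroxide- and superoxide-removing enzyme genes Prdx1 and Sod1 had 4890 and 3515 and 6473 and 5547. Heat shock genes had a median of -0.27 over 18 genes, 13 of them below 0 (interval -0.47 to 0.00, percentile 2.01; -0.16 under quantile normalization, inside the central range), with the co-chaperones Chordc1 at 805 and 555 and Dnaja1 at 3086 and 2221. Endoplasmic reticulum and integrated stress genes had 0.07 over 28, 16 of them above 0 (interval -0.05 to 0.21, percentile 98.8; 0.16 under quantile normalization, 0.13 with upper-quartile scaling), with Pdia4 at 271 and 375 and Canx at 2468 and 2084. Autophagy genes had 0.01 over 25 genes (percentile 93.9; 0.10 under quantile normalization), with Lamp2 at 3458 and 2687 and Gabarap at 2461 and 1910.

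In the circadian list, Nr1d1, the repressor REV-ERB alpha, rose from 981 to 1488 (log2 ratio 0.60, PPEE 0.00412 in the authors' deposited table) while Nfil3 fell. The other 15 measured members were not called (median of the 17 0.02, percentile 85.0; 0.10 under quantile normalization). Glucocorticoid-response genes had a median of -0.08 over 18 (percentile 47.1; 0.03 under quantile normalization), with 1 rise, Klf15. Insulin and glucose genes had -0.15 over 25 (percentile 49.4; -0.04 under quantile normalization, -0.09 with upper-quartile scaling), with Pfkl at 2470 and 1445 and Irs1 at 410 and 525. Proliferation genes had -0.01 over 20 (percentile 44.8; 0.05 with upper-quartile scaling), with Mki67 at 20.1 and 34.3 and Ccna2 at 85.2 and 66.6. Immediate early genes, which respond within minutes to stimuli, had 0.13 over 19 (percentile 96.1; -0.05 with a minimum mean of 50, the opposite direction), with Socs3 at 26.5 and 46.5 and Klf4 at 387 and 555. Epithelial markers had -0.13 over 5 (percentile 17.7; -0.07 with upper-quartile scaling; Krt10 at 38.1 and 27.6, Trp63 at 45.1 and 38.7). Erythroid markers had -0.15 over 5 (percentile 47.6; 0.03 under quantile normalization; Hbb-b1 at 1412 and 1138, Alas2 at 127 and 134), and nerve markers -0.02 over 11 (percentile 49.0; 0.09 under quantile normalization, -0.22 with a minimum mean of 50; Mal at 51.5 and 35.6, Prx at 46.9 and 65.5). The mesothelial list had 1 measured gene, Gpm6a at 14.8 and 12.7. The sex-linked list had 4, with Eif2s3y at 1038 and 836 and Uty at 339 and 290. The 13 genes of the mitochondrial genome were not analysed here.

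Of the 32 lists with at least 5 measured members, 16 had medians outside the central 95% of matched random lists, 9 low and 7 high. If genes were independent, 1.6 would lie outside by chance. The medians of 5 lists inside the central range (NRF2, glucocorticoid, proliferation, erythroid and nerve) changed sign under quantile normalization. Members of a pathway vary together between animals, so a percentile describes these group means and is not a test across mice. Among the 305 genes with an absolute log2 ratio of at least 1, 276 had a PPEE above 0.5 in the authors' deposited table.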

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

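The PPEE bounds of 0.01 and 0.1 and the length alternatives were chosen after the results were seen. The others were fixed before the data were examined, but the random-list method they were applied to was not. Requiring an absolute log2 ratio of at least 1 left 11 called genes, 6 higher and 5 lower, and a PPEE of at most 0.01 left 63, 32 higher and 31 lower, both because the bound is stricter; at 0.1 there were 119, 63 higher and 56 lower. A minimum mean of 50 left 97, 50 higher and 47 lower. Under quantile normalization of the means 53 calls were higher and 46 lower, Rpl6 moving from -0.23 to 0.04 (this gene and the 3 in the next sentence were named because their sign changed). After length adjustment the called Rpl29, Rps26 and Rps10 moved above 0, to 0.03, 0.06 and 0.08. Of 98 named genes, 97 kept their sign under quantile normalization and under upper-quartile scaling, 98 with a constant of 0.1, and 96 after length adjustment, with no called gene among the exceptions. The number of lists outside the central 95% was 16 under each planned setting, 17 with random lists matched also on length and 19 with length-adjusted ratios. Upper-quartile scaling shifted all ratios by nearly the same amount (0.059 at the median), random lists included, so it could hardly move a percentile. The constant of 0.1 shifted the median ratio by -5.59e-05 and cannot change a sign. Unchanged results under these settings are therefore no sign of robustness. Heat shock entered the central range under quantile normalization, and skeletal muscle left it there and with length matching. With a minimum mean of 50 the equal number hid an exchange: smooth muscle left the central range, while the B cell list, low in the report, had too few members for a percentile, as had the T and NK cell and epithelial lists. With length-adjusted ratios the antioxidant, immediate early and T and NK cell lists left it. The medians of 5 lists inside the central range changed sign under quantile normalization, 3 (metal, proliferation and nerve) under upper-quartile scaling, 2 (immediate early and autophagy) with a minimum mean of 50 and 4 (antioxidant, proliferation, erythroid and nerve) with length-adjusted ratios, and that of no list outside it did. PPEE cannot be recomputed from group means, so the scalings, the constant of 0.1 and the length adjustment were applied to ratios alone. Size-factor scaling of single libraries, other count or linear models, robust and non-robust fits, another unit, an estimated correlation, a self-contained set test, marker levels per mouse, a relaxed filter and leaving out replicates were not run, since they need values per mouse. No paired analysis was possible because the groups share no replicate number.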

Other observations

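The tests of muscle share, thermogenic adipocytes, main cell type, endothelial share and lymph node tissue were chosen after the values were seen, while the bounds of the gene length and shared sequence tests were set before their results. Genes in the next paragraphs that the report does not name were picked after their values were seen, and none of them was called unless stated.

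Mest, an imprinted gene linked to adipocyte enlargement, had authors' means of 539 under water and 2304 under arsenite. Sfrp5, a secreted Wnt inhibitor, had 85.2 and 497, and Peg3, another imprinted gene, 289 and 1057. The PPEE of Mest, Sfrp5 and Peg3 was 0.968, 0.883 and 0.795 in the authors' deposited table. Of polyamine metabolism, Odc1, ornithine decarboxylase, had means of 1947 and 952 and Amd1, S-adenosylmethionine decarboxylase, 7373 and 3262. Smox, spermine oxidase, had 810 and 286, while Srm, spermidine synthase, had 215 and 234. The 11 major urinary protein genes all had ratios below 0 with a median of -1.39, 1 of them called, but Mup19 shares its sequence with other members, so their values are not independent. The lipid droplet gene Plin2 had means of 10888 and 6147 with a PPEE of 0.107, and Idi1, of cholesterol synthesis, 1285 and 596 with a PPEE of 0.0908, in the authors' deposited table.

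Muscle genes differed in direction. Beside the lower means of Myh4 and Acta1 under arsenite, Mybpc1, of slow-type myosin binding protein C, had 34.2 and 276 and Actn2, a sarcomeric actinin, 66.0 and 165. Of the clock genes, Arntl had means of 73.5 and 52.2, Per2 310 and 327 and Dbp 638 and 755. The 76 measured mitochondrial ribosomal protein genes had a median log2 ratio of -0.40, or -0.25 after the length trend was removed, and 1 of them, Mrpl17, was called lower.

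After the trend of ratio on gene length was removed, the median of the oxidative phosphorylation list, low among the mitochondrial groups, was -0.34 (interval -0.40 to -0.29), which argues against length as its whole cause. That of 76 cytosolic ribosomal protein genes was 0.0069 (interval -0.033 to 0.035), so their lower calls may follow the length trend. Against random lists matched on level and length, their deposited median lay at percentile 99.9, not lower than genes of like length and level. The length trend may be technical, which was not tested. The tricarboxylic acid cycle median, length-adjusted, lay -0.29 from that of the skeletal muscle markers (interval -0.39 to -0.15). In these group means this argues against a smaller share of adjoining muscle as the whole cause of that part. Intervals here and in the next paragraph are over list members and hold no spread between mice. The oxidative phosphorylation median lay -0.23 from the muscle median as deposited (interval -0.35 to -0.11) but -0.11 after length adjustment (interval -0.22 to 0.02), so for this part muscle and length together stay open. Fewer or less active thermogenic adipocytes stay open: the length-adjusted thermogenic median of -0.62 (interval -0.95 to -0.34) restates a list already seen to lie low, and none of its genes was called. The thermogenic and fatty acid oxidation lists were not set against the muscle markers, so a part of muscle share in their low medians was not tested.

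The high endothelial markers had a median of 0.67 (interval 0.58 to 0.79) after length adjustment, which argues against the length trend. A lower share of the main cell type would raise other resident cells alike, but endothelial exceeded macrophage markers by 0.70 (interval 0.59 to 0.88). Only macrophages were compared, while preadipocyte and fibroblast markers lay high as well (median 0.17), so this test does not cover all resident cells. General adipocyte genes had a median of 0.26 (interval 0.08 to 0.36), with 20 above 0 and 9 below, so as a list they did not fall. Ratios are relative and no bound was set for this comparison, so it does not decide on adipocyte share. A larger endothelial share of the tissue and higher expression per endothelial cell both stay open, since the 94.4% of endothelial markers above 0 after adjustment restates the pattern and decides nothing between them.

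The listing of Ccl21a at 0 under arsenite was set against reads shared with copies and against lymph node tissue. Of its 50-base stretches, 71.6% also occur in other genes, between the bounds of 90% and 10% set for this test, so an assignment of its reads to copies cannot be told apart from a loss of transcript; the copies were not analysed here. Less lymph node in the dissected depot stays open too. The lowest of 19 T, NK and B cell markers had a log2 ratio of -1.35 in the authors' deposited table and their median was -0.29. Ccl21a had -7.12 in the authors' deposited table, so these markers did not fall as far. The size of that ratio depends on the added constant, and its 0 may come from read assignment. The markers also had low means, so the comparison does not decide. The lymph node chemokine Ccl19 had means of 49.6 and 17.1.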
